A study of Mus musculus with 6 samples.

How the data were processed

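Total RNA was purified with an RNeasy Micro kit, labelled with biotin and hybridised to Affymetrix GeneChip arrays, per the labels' protocols. The series design text names GeneSpring for the authors' analysis and Flk1+/GFP embryos among the sources. How the Flk1-positive cells were selected is not given in the sources used here. The deposited values are a linear probe-set signal for 45101 probe sets on each of 6 arrays. The trimmed mean over each array (2% left out at each end) was 500 on all 6, and the lowest value was 1, so the values were scaled to a common level and have a floor before deposit; which program made and scaled them is not given in the sources used here. The deposited table held no detection calls and no scanner intensities were used here. Fewer than 2% of the values of any array were at the floor of 1.

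Probe sets were named from the platform annotation: 34958 had 1 gene symbol, 932 had several and 9211 had none, and only those with 1 symbol were named. Through their gene ID, 34754 symbols were found in a RefSeq gene table, and none changed. A gene was represented by its probe set with the highest mean over the 6 arrays, and other probe sets of a gene can differ from it in call. No coordinates are given, since no genome build is named in the files.

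Signals were transformed as log2(signal + 21.61), where the pseudocount is the 25th percentile of all values. The deposited scale was kept, because the array medians lay within 0.187 on the log2 scale, inside the limit of 0.2 set beforehand. The 64 control probe sets were left out, and 33778 probe sets of 14949 genes with a mean at or above the 25th percentile were tested. A linear model with group as the only term was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 3 residual and 2.49 prior degrees of freedom), with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. Groups share 1 estimate of the spread because each has 2 arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

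The background level was the 95th percentile of 80 olfactory and vomeronasal receptor probe sets on each array, averaged over the arrays (6.30 on the log2 scale, a signal of 57.4). Where the dimmer group's mean lay below it, the difference is given as at least the fold between the brighter group's mean and this level. Array correlations within groups, RNA control probe sets and the targeted gene were checked.

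Before the data were examined, 22 gene lists were fixed: endothelial, arterial, venous and lymphatic, primitive erythroid, other blood cells, cardiomyocyte, endocardium, mural and mesenchymal, neuroectoderm, neural crest, somite and presomitic mesoderm, gut endoderm, yolk sac endoderm, immediate early and heat shock, hypoxia and glycolysis, Notch signalling, BMP and TGF-beta response, cell cycle, p53 and apoptosis, basement membrane and matrix, Hox genes and sex-linked genes. They were tested with camera at a preset correlation of 0.01, adjusted over the 22 lists of each comparison. They were tested again with a correlation estimated from the 3 residual degrees of freedom. In this second form the test statistic also has only 3 degrees of freedom, while in the first these follow the number of genes. Genes not tested and those without a match on the array were left out of their list. Named genes followed a rule fixed at the same time: Kdr; the 10 largest rises and falls past the test with arrays that do not overlap and a brighter mean above background, or by size as values where fewer than 5 passed; up to 2 rising and 2 falling members of each list; and the 15 widest genes of the set ordered by size. Clone names were left out. The rule orders genes by log2 value, also where the dimmer mean lies below background, so its order is not one of fold. That set required at least 2-fold differences and every Flk1-positive array above every WT array above every Flk1 KO array, which is 1 of 90 orderings.

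Because both comparisons with WT embryos share the same 2 arrays, 100 simulations were run in which no group differed. All 6 arrays were drawn anew around each probe set's mean, and both comparisons used the same simulated WT arrays. The simulations give the overlap and correlation of groups without differences, not those that shared controls produce where Flk1-positive cells differ. The alternatives tried were the pseudocount (10th percentile and median), the filter (none and 50th percentile), quantile normalization and median centring, an intensity trend with a robust prior, only the 2 groups compared, a replicate block, 1 probe set per gene, the median over a gene's probe sets, a 2-fold limit, other fold limits for the set ordered by size, an estimated correlation and leaving out each array. The procedure was tested on simulated data over 33778 probe sets: for Flk1-positive cells against WT embryos it recovered 94% of 4-fold and 21% of 2-fold changes with 7 false calls of 171. For Flk1 KO against WT embryos it recovered 90% and 20% with 3 false calls of 154. The adjusted threshold depends on the number of calls. In the data this was 27 lower for Flk1 KO, and 3924 higher and 4879 lower for Flk1-positive cells, each against WT embryos. The recovered shares therefore do not carry over to either comparison, and the threshold for Flk1 KO was stricter than in its simulation. Of 200 simulated lists with no change, 6 had a camera p under 0.05. These lists were drawn at random from probe sets simulated independently of each other. The count therefore does not show how the test behaves for lists whose genes change together.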

Results

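Gene expression was measured on Affymetrix mouse arrays in ICR mouse embryos at 8.5 days post coitum, at the 3 to 4 somite stage, before blood begins to circulate. The 6 arrays formed 3 groups of 2 arrays each: cells positive for Flk1 (the VEGF receptor encoded by Kdr, found on endothelial cells and their precursors), embryos with a knockout of Flk1 (Flk1 KO) and wild-type (WT) embryos. Embryo groups were the embryo proper, and the series is about genes enriched in the endothelial cells of the embryo. Each array reported 45101 probe sets, and 54.3% to 57.8% of them lay above the background level, set at a signal of 57.4 from olfactory and vomeronasal receptor probe sets. The number of arrays limits the precision. The labels do not say that the arrays of a group came from separate animals or pools. Limma p-values therefore measure only the spread between these samples, which may be technical. Camera p-values at the preset correlation compare the genes of a list with the other genes, counting genes nearly as independent replicates. They do not measure the spread between embryos. Differences are on the log2(signal + 21.61) scale, which understates the change of dim genes, and are given as log2 value ± SE from limma with 2 arrays per group.

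The targeted gene followed the labels on all 6 arrays. The Kdr probe set had signals of 3309 and 3328 in Flk1-positive cells, 543.9 and 545.5 in WT embryos, and 29.5 and 63.8 in Flk1 KO embryos. Kdr was 2.56 ± 0.25 higher in Flk1-positive cells than in WT embryos (limma adjusted p = 0.00192). The Flk1 KO mean of 46.6 was not above the background level, so Kdr was at least 7.17-fold lower in Flk1 KO than in WT embryos (limma adjusted p = 0.0459). Where this probe set lies relative to the targeted part of the gene is not given in the sources used here. Kdr encodes the receptor that the cells are named for and is the gene knocked out, so it checks the labels and is no finding. The design text names Flk1+/GFP embryos among the sources, and the genotype label of the cells reads only Flk1 positive cell. A difference in genotype between these cells and WT embryos therefore cannot be told apart from the group.

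**Figure D1:**
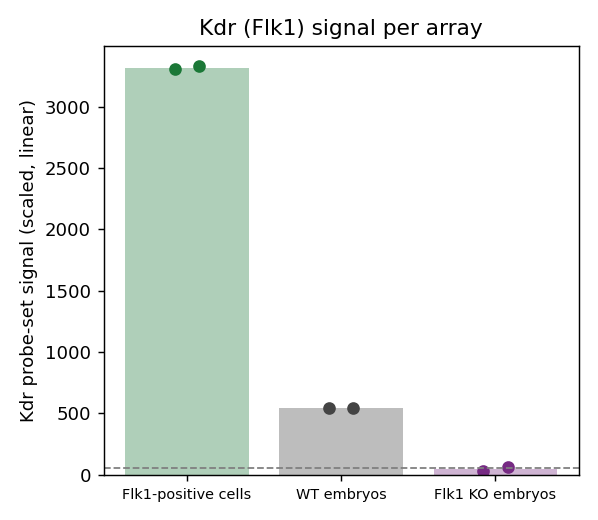
Kdr probe-set signal on a linear scale (vertical axis) on each array (points) with the group mean (bars) for Flk1-positive cells, WT embryos and Flk1 KO embryos, 2 arrays each; the dashed line is the background level of 57.4. The 2 Flk1-positive arrays sit at 3309 and 3328, the WT arrays at 543.9 and 545.5, and the Flk1 KO arrays at 29.5 and 63.8.

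Flk1-positive cells were compared with WT embryos to find transcripts enriched in them. They differed widely: 3924 probe sets were higher and 4879 lower, of 33778 tested, covering 2245 and 3241 genes. By log2 value, the rule fixed for naming genes, the rises at the top were in Lyve1, a hyaluronan receptor (6.90 ± 0.14), and in the embryonic globins Hba-x (6.44 ± 0.57) and Hbb-bh1 (6.35 ± 0.34). They were followed by Oit3 (at least 48.8-fold), the endothelial lectin Clec14a (at least 40.7-fold), the GTPase Gimap4 (4.96 ± 0.30), the mannose receptor Mrc1 (4.89 ± 0.13), the immediate early gene Fos (4.86 ± 0.21), the protein C receptor Procr (4.67 ± 0.16) and the scavenger receptor Stab2 (4.54 ± 0.30). Named by the same rule among the falls were the posterior patterning gene Cdx1 (at least 18.8-fold lower) and Sox2, a transcription factor of neural progenitors (-5.80 ± 0.30). Eras, Epcam, Ntn1 and Esrp1 were at least 18.0-fold, 16.9-fold, 19.3-fold and 16.4-fold lower, and Irs4 (-5.07 ± 0.16), Arg1 (-5.0 ± 0.15), Sp8 (at least 9.57-fold lower) and Hoxc4 (at least 9.02-fold lower) were named as well, and where only a bound is given the rank is uncertain. All 20 of these genes had limma adjusted p-values of 0.0014 or below, with arrays that did not overlap between the groups. The counts depended on single arrays: without Flk1-positive replicate 1 or 2 they were 2049 higher and 3070 lower, and 2159 higher and 2890 lower. Without WT replicate 1 or 2 they were 2155 higher and 2210 lower, and 2249 higher and 2225 lower.

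The vascular gene lists were higher in Flk1-positive cells. All 43 members of the endothelial list were higher, over all genes tested and adjusted over the list alone, with a median of 3.36 (10.3-fold; camera adjusted p = 3.68e-32, and adjusted p = 0.0536 with an estimated correlation). Clec14a and Stab2 led. Of 16 arterial genes, 8 were higher and 2 lower in either count, with a median of 0.69 (camera adjusted p = 0.000702, and adjusted p = 0.117 with an estimated correlation). The gap junction gene Gja4 (3.07 ± 0.16) and the receptor Notch4 (2.82 ± 0.22) were higher, while the chemokine Cxcl12 (-2.26 ± 0.20) and its receptor Cxcr4 (-1.21 ± 0.14) were lower. Of 8 venous and lymphatic genes, 5 were higher in either count, with a median of 1.25 (camera adjusted p = 0.000717, and adjusted p = 0.0818 with an estimated correlation). Among them were Lyve1 and the VEGF receptor Flt4 (2.98 ± 0.13). Of 7 endocardial genes, 6 were higher in either count, with a median of 2.11 (camera adjusted p = 0.000944, and adjusted p = 0.117 with an estimated correlation). They included the flow-responsive factor Klf2 (3.64 ± 0.18) and the matrix link protein gene Hapln1 (2.48 ± 0.16), and the cardiac transcription factor Gata5 was lower (-1.50 ± 0.16). In the basement membrane and matrix list, 14 of 18 genes were higher and 1 lower in either count, with a median of 1.28 (camera adjusted p = 6.77e-09, and adjusted p = 0.0536 with an estimated correlation). Nid1 (3.81 ± 0.16) and the laminin gene Lama4 (3.34 ± 0.16) were higher and Lama5 was lower (-0.97 ± 0.17), a call lost without Flk1-positive replicate 1 or WT replicate 1.

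Blood cell genes and immediate early genes were higher as well. Of 16 primitive erythroid genes, 12 were higher and 2 lower in either count, with a median of 2.42 (camera adjusted p = 2.94e-06, and adjusted p = 0.0818 with an estimated correlation). Hba-x and Hbb-bh1 led. Rhd (at least 1.11-fold lower) and Bpgm (-0.83 ± 0.19) were lower, calls that ended when single arrays were left out. Globin probe sets can share signal with closely related globins. Of 19 genes of other blood cells, 13 were higher (16 adjusted over the list alone), with a median of 1.91 (camera adjusted p = 8.55e-10, and adjusted p = 0.087 with an estimated correlation). Plek (at least 18.3-fold) and Lyl1 (3.76 ± 0.40) were among them. Of 20 immediate early and heat shock genes, 14 were higher and 1 lower (15 and 1 adjusted over the list alone), with a median of 1.63 (camera adjusted p = 2.11e-08, and adjusted p = 0.0536 with an estimated correlation). Fos and Egr1 (3.29 ± 0.15) were higher, and the heat shock gene Hspb1 was lower (-0.88 ± 0.17), a call lost without Flk1-positive replicate 2 or WT replicate 1. Of 16 BMP and TGF-beta response genes, 8 were higher and 1 lower in either count, with a median of 0.54 (camera adjusted p = 0.00358, and adjusted p = 0.087 with an estimated correlation). The coreceptor Eng (3.83 ± 0.21), also an endothelial list member, and Tgfb1 (3.66 ± 0.18) were higher, and Id2 was lower (-2.25 ± 0.14). RNA control probe sets moved with the group. The 3' minus 5' log2 difference of the transferrin receptor control was 1.33 and 1.44 in Flk1-positive cells against 0.97 to 1.09 on the other 4 arrays. For Actb it was 0.26 and 0.29 against 0.47 to 0.58, and that of Gapdh lay between -0.37 and -0.32 on all arrays.

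Markers of the other tissues of the embryo were lower in Flk1-positive cells. In the gut endoderm list all 15 genes were lower in either count, with a median of -3.13 (camera adjusted p = 9.24e-11, and adjusted p = 0.0712 with an estimated correlation). The epithelial genes Epcam and Cdh1 (-4.40 ± 0.24) led. In the neuroectoderm list 20 of 22 were lower and 1 higher in either count, with a median of -2.36 (camera adjusted p = 1.51e-09, and adjusted p = 0.0712 with an estimated correlation). Sox2 and Sp8 led. Nes, which encodes an intermediate filament also known from endothelial cells, was higher (0.94 ± 0.18), a call lost on leaving out any 1 Flk1-positive or WT array. In the neural crest list 9 of 12 were lower and 1 higher in either count, with a median of -2.15 (camera adjusted p = 0.000188, and adjusted p = 0.0791 with an estimated correlation). With group means below background set to that level the neural crest median was -1.52. Pax3 and Pax7 were at least 6.55-fold and 2.81-fold lower, and the endothelin receptor Ednrb was higher (2.16 ± 0.13). In the somite and presomitic mesoderm list 16 of 22 were lower (18 lower and 1 higher adjusted over the list alone), with a median of -2.09 (camera adjusted p = 2.65e-07, and adjusted p = 0.0536 with an estimated correlation). The somite median was -1.26 with group means below background set to that level. Aldh1a2 (-3.94 ± 0.18) and Meox1 (-3.59 ± 0.16) led. In the cardiomyocyte list 19 of 28 were lower and 1 higher (21 and 1 adjusted over the list alone), with a median of -1.61 (camera adjusted p = 7.69e-07, and adjusted p = 0.1 with an estimated correlation). The contractile genes Myh6 and Myl3 were at least 14.2-fold and 8.16-fold lower, and the transcription factor Mef2c, which endothelial cells also use, was higher (1.52 ± 0.13). In the yolk sac endoderm list 14 of 17 were lower (15 adjusted over the list alone), with a median of -1.30 (camera adjusted p = 6.82e-06, and adjusted p = 0.0712 with an estimated correlation). Fgb and Maob were at least 2.06-fold and 3.40-fold lower. In the mural and mesenchymal list 5 of 13 were lower in either count, with a median of -0.39 (camera adjusted p = 0.0358, and adjusted p = 0.137 with an estimated correlation). They included Pdgfra (-2.96 ± 0.25) and the smooth muscle gene Cnn1 (at least 2.70-fold lower). This call was also lost with the stricter filter (adjusted p = 0.0943) and without Flk1-positive replicate 2 (adjusted p = 0.0521). The median depended on single arrays: -0.99 and -0.25 without Flk1-positive replicate 1 and 2, and -0.83 and -0.23 without WT replicate 1 and 2.

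The remaining lists did not pass the camera test in this comparison. Of 22 Hox genes, 2 were higher and 10 lower (3 and 11 adjusted over the list alone; camera adjusted p = 0.0597). Hoxb5 (2.16 ± 0.14) and Hoxd8 (1.03 ± 0.14) were higher and Hoxb1 lower (-3.44 ± 0.27). Several alternative settings brought this list past the threshold. Of 18 Notch signalling genes, 6 were higher and 7 lower in either count, with Mfng higher (2.30 ± 0.15) and Dtx4 lower (-3.05 ± 0.20). The median was -0.06 while camera pointed upward (camera adjusted p = 0.526). Hes5, a Notch target, was at least 2.77-fold lower, a call lost without either WT array. Of 18 hypoxia and glycolysis genes, 2 were higher and 3 lower in either count (camera adjusted p = 0.656). Egln3 (1.41 ± 0.16) and Adm (0.68 ± 0.15) were higher and Bnip3 (-0.95 ± 0.17) and Hk2 (-0.90 ± 0.14) lower, and all of these except Egln3 lost their calls when single arrays were left out. Of 13 p53 and apoptosis genes, 2 were higher and 3 lower in either count (camera adjusted p = 0.526). Eda2r (1.46 ± 0.26) and Ccng1 (0.97 ± 0.24) were higher and Pmaip1 (-1.83 ± 0.23) and Zmat3 (-0.68 ± 0.12) lower. Of these 4 calls, that of Pmaip1 alone held when single arrays were left out. Of 23 cell cycle genes only Mcm7 was lower (-0.46 ± 0.12), a call lost on leaving out any 1 Flk1-positive or WT array, with none adjusted over the list alone (camera adjusted p = 0.432). None of the 4 sex-linked genes passed in either count (camera adjusted p = 0.879, with a median of -0.22 against an upward camera direction). Xist differed by 0.64 ± 0.35 and Uty by -0.41 ± 0.38.

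**Figure D2:**
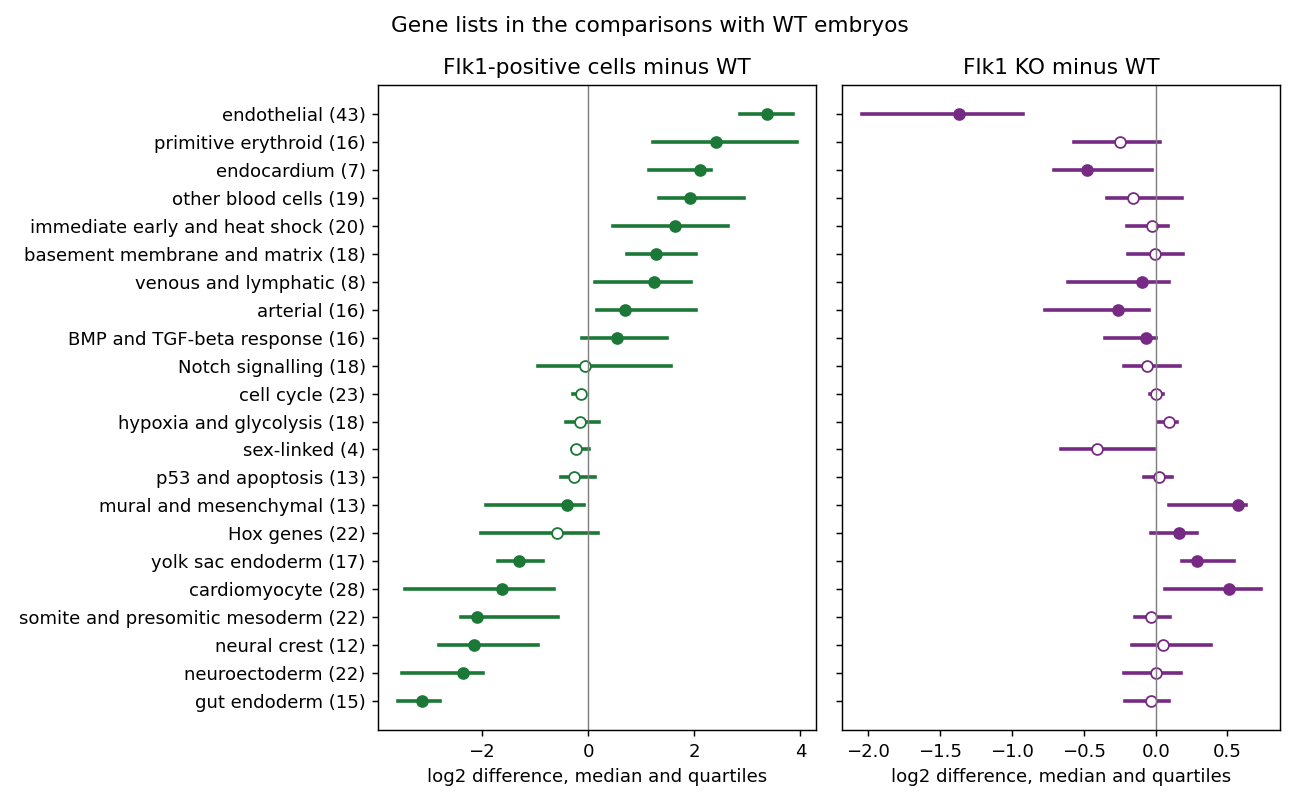
Median (circle) and quartiles (line) of the log2 difference over the tested members of each gene list, with the number of members in brackets, for Flk1-positive cells minus WT embryos (left) and Flk1 KO minus WT embryos (right), 2 arrays per group; filled circles have a camera adjusted p under 0.05 at the preset correlation of 0.01. The endothelial list has the highest median on the left (3.36) and the lowest on the right (-1.37).

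Flk1 KO embryos were compared with WT embryos to find what the loss of the receptor changes. In all, 27 probe sets of 26 genes were lower. Of these genes 13 belong to the endothelial list, and 26 of the 27 probe sets were higher in Flk1-positive cells. Kdr itself, which is in no list, is counted in the 27 and in the 26. The genes named after Kdr had Flk1 KO means mostly not above the background level, so they are not ranked. The adhesion gene Esam was at least 5.92-fold lower, the blood and endothelial transcription factor Tal1 at least 4.70-fold. The transcription factors Erg, Sox7 and Sox18 were at least 2.25-fold, 4.61-fold and 5.14-fold lower, the tight junction gene Cldn5 at least 4.71-fold and the receptor Tie1 at least 1.84-fold. The vesicle diaphragm gene Plvap (-2.57 ± 0.19) and the receptor Flt4 (-2.54 ± 0.13) were lower at levels above background in both groups. Limma adjusted p-values of these 9 genes lay between 0.02 and 0.043. The 1 exception, named after its values were seen, was a probe set of the DNA repair gene Fancc, at least 1.69-fold lower in Flk1 KO and without a call in Flk1-positive cells (0.10). The brightest Fancc probe set had no call (-0.11 ± 0.28). For Lyve1, Gimap4 and Mmrn2 the brightest probe set had no call either, while another was at least 1.27-fold, 2.09-fold and 3.72-fold lower (limma adjusted p = 0.0427, 0.0427 and 0.02). No probe set was higher with limma, whose smallest adjusted p in that direction was 0.0636, while 837 probe sets were higher and 1997 lower at an unadjusted p under 0.05. These single-gene calls were fragile: leaving out any 1 of the 6 arrays left 0 calls, as did the smaller pseudocount and the fit on these 2 groups alone. An intensity trend with a robust prior gave 121 lower and 13 higher.

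As a set, the endothelial genes fell in Flk1 KO embryos. Of 43 genes, 12 were lower over all genes tested and 39 adjusted over the list alone, and both Flk1 KO arrays lay below both WT arrays for 40. The median was -1.37, or -1.12 with group means below background set to that level (camera adjusted p = 2.36e-62). This was the only call of the 9 in this comparison that held with an estimated correlation (adjusted p = 0.0446). The arterial list was lower (1 of 16 genes, Gja4, at least 2.86-fold; 4 adjusted over the list alone; median -0.26; camera adjusted p = 3.69e-05, and adjusted p = 0.196 with an estimated correlation). The endocardial list was lower with 0 of 7 genes called and 3 adjusted over the list alone (median -0.48; camera adjusted p = 0.00261, and adjusted p = 0.226 with an estimated correlation). Hapln1 differed by -0.90 ± 0.16 and Nfatc1 by -0.78 ± 0.18. That call was lost with the median over each gene's probe sets (adjusted p = 0.13), where Nfatc1 also changed sign. Without Flk1 KO replicate 2 the endocardial median was -0.23 and the arterial one -0.46. The venous and lymphatic list (1 of 8 lower, Flt4; 3 adjusted over the list alone) and the BMP and TGF-beta list (0 of 16; 4 lower adjusted over the list alone) passed camera downward (adjusted p = 0.0327 for each, and adjusted p = 0.226 for each with an estimated correlation). Their medians were -0.10 and -0.07, and both calls were lost without Flk1 KO replicate 2 (adjusted p = 0.237 and 0.278), the venous one also without either Flk1-positive array or WT replicate 2. On leaving out single arrays the medians ranged from -0.27 to -0.06 and from -0.16 to -0.02. The largest BMP and TGF-beta values were Eng at -1.26 ± 0.21 and Tgfb1 at -0.87 ± 0.18, neither past the test.

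Cardiac, mesenchymal and yolk sac endoderm lists passed camera upward in Flk1 KO embryos, with no single gene past the test over all genes. The cardiomyocyte list had a median of 0.51 over 28 genes (3 higher adjusted over the list alone, 19 with both Flk1 KO arrays above both WT arrays; camera adjusted p = 3.74e-08, and adjusted p = 0.196 with an estimated correlation). The ventricular light chain genes Myl2 and Myl3 differed by 1.69 ± 0.33 and 1.08 ± 0.43. The mural and mesenchymal list had a median of 0.57 over 13 genes (3 higher adjusted over the list alone; camera adjusted p = 5.45e-07, and adjusted p = 0.118 with an estimated correlation). Postn was at 1.37 ± 0.19 and the collagen gene Col3a1 at 1.33 ± 0.19. The yolk sac endoderm list had a median of 0.29 over 17 genes (4 higher adjusted over the list alone; camera adjusted p = 1.91e-05, and adjusted p = 0.164 with an estimated correlation). Afp was at 1.13 ± 0.17 and S100g at 1.03 ± 0.22. The Hox list had a median of 0.16 over 22 genes (0 adjusted over the list alone; camera adjusted p = 0.0364, and adjusted p = 0.383 with an estimated correlation). Hoxa7 was at 1.74 ± 0.60 and Hoxc9 at 0.60 ± 0.42. The Hox call was lost under quantile normalization (adjusted p = 0.093), median centring (adjusted p = 0.0907) and no filter (adjusted p = 0.0721), and without Flk1 KO replicate 1 (adjusted p = 0.329) or WT replicate 2 (adjusted p = 0.253). Without Flk1 KO replicate 1 the medians were 0.32 for the cardiomyocyte, 0.27 for the mural and mesenchymal and 0.07 for the Hox list. The Hox median was 0.28 without WT replicate 1. Among the single differences upward that did not pass were Shisa3 (at least 2.08-fold, adjusted p = 0.24), Hoxa7, Fsd2 (at least 2.10-fold) and Myl2. Neurog2, a neuronal transcription factor, was at least 1.61-fold higher (adjusted p = 0.10).

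Blood and the other tissue lists did not pass in Flk1 KO embryos. The primitive erythroid list had a median of -0.25 over 16 genes, 1 lower adjusted over the list alone (camera adjusted p = 0.076). Of these genes 10 lay below background in Flk1 KO and 6 in WT embryos, and with such means set to background the median was -0.04. Hbb-bh1 and Hbb-y were at least 4.47-fold and 2.64-fold lower by their brightest probe sets, neither past the test. A second Hbb-bh1 probe set was past it (at least 3.06-fold lower, limma adjusted p = 0.0224). For other blood cells the median was -0.15 over 19 genes (camera adjusted p = 0.324), or -0.05 with group means below background set to that level. Lyl1 was at least 2.54-fold lower. Tyrobp (0.79 ± 0.29) had both means below background, so its size cannot be read, and neither gene passed the test. Several settings brought these 2 lists past the threshold. On leaving out single arrays the erythroid median ranged from -0.27 to -0.05 and that of other blood cells from -0.34 to 0.02. The medians lay within 0.1 of 0 for neuroectoderm (camera adjusted p = 0.634), neural crest (0.477), somite and presomitic mesoderm (0.958), gut endoderm (0.656), immediate early and heat shock (0.656), hypoxia and glycolysis (0.222), Notch signalling (0.252), cell cycle (0.958), p53 and apoptosis (0.824) and basement membrane and matrix genes (0.958). Adjusted over the list alone, 1 Notch signalling gene was lower and none in the other 9 lists passed. For the somite and the basement membrane lists the median (-0.03 and -0.00627) and camera's direction differed in sign. The 2 neuroectoderm genes with the largest values were Zic1 (1.25 ± 0.29) and En2 (1.0 ± 0.20). None of the 4 sex-linked genes passed (median -0.41, from -0.91 to -0.02 on leaving out single arrays; camera adjusted p = 0.569).

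Flk1-positive cells were also set directly against Flk1 KO embryos, whose endothelial transcripts were low. Here 4673 probe sets were higher and 5195 lower (2483 and 3488 genes). These counts exceeded those against WT embryos, but with only the 2 groups compared they were smaller, 3853 and 3976 against 4047 and 4886. Hbb-bh1 was at least 365-fold higher, Lyve1 at least 122-fold, Hba-x at least 105-fold, Esam at least 89.4-fold and the protease inhibitor gene Ctla2a at least 75.2-fold. Gimap4, Cd93, Ctla2b, Oit3 and Tie1 were at least 63.7-fold, 61.9-fold, 50.3-fold, 48.8-fold and 30.5-fold higher. Sox2 (-5.56 ± 0.30), Irs4 (-5.16 ± 0.16), Arg1 (-5.14 ± 0.15) and the retinoic acid binding protein gene Crabp2 (-4.78 ± 0.24) were lower. Cdx1, Epcam, Eras, Ntn1, Myh6 and Myl3 were at least 11.3-fold, 19.5-fold, 14.6-fold, 21.3-fold, 26.5-fold and 17.3-fold lower. Limma adjusted p-values of these genes were 0.0012 or below. All 43 endothelial genes were higher in either count, with a median of 4.92 (camera adjusted p = 1.51e-35, and adjusted p = 0.06 with an estimated correlation). Of 28 cardiomyocyte genes 22 were lower and 1 higher (23 and 1 adjusted over the list alone), with a median of -2.20 (camera adjusted p = 6.78e-08, and adjusted p = 0.0764 with an estimated correlation). In all, 17 of 22 lists passed camera, 9 upward and 8 downward, and none held with an estimated correlation (adjusted p from 0.06 to 0.167). Without Flk1-positive replicate 1 or 2 the counts fell to 2521 higher and 3376 lower, and to 2785 higher and 3288 lower.

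Requiring both enrichment in Flk1-positive cells and loss in Flk1 KO embryos, at 2-fold or more each and with no overlap between the arrays of the 3 groups, gave 129 probe sets of 93 genes. Of these genes 33 belong to the endothelial list, 3 to the arterial, 2 to the venous and lymphatic, 2 to the primitive erythroid and 1 to the other blood cell list, and 52 were in no list. By log2 span between Flk1-positive cells and Flk1 KO embryos the rule named Hbb-bh1, Lyve1, Ctla2a, Oit3, Gimap4, Mmrn2, Esam, Ctla2b, Tie1, Cd93, Icam2, Hbb-y, Sox18, Clec14a and Mrc1, an order that rests on Flk1 KO means below background and is not one of fold. Of the 15, Ctla2a had values of 4.36 ± 0.30 against WT embryos in Flk1-positive cells and at least 3.66-fold lower in Flk1 KO embryos, and for the adhesion gene Icam2 these were 4.53 ± 0.20 and at least 2.67-fold. The opposite order, Flk1 KO above WT above Flk1-positive cells, held for 10 probe sets of 8 genes, among them Myl2, Myl3, Afp, En2 and Zic1. This is a rule of size with no p-value. Simulated groups that did not differ gave 0.1 probe sets on average, and at most 1, for the first order and 0.08 for the opposite one. In the data 2198 probe sets were called at least 2-fold higher in Flk1-positive cells. These need only a fall in Flk1 KO embryos to enter the set. The simulated counts are therefore too low as the number that noise alone would bring into it. Calls higher in Flk1-positive cells and lower in Flk1 KO embryos overlapped in 26 probe sets, against 3.14 for independent lists. Kdr, which only checks the labels, is counted in the 26 and also meets the rule of the set. The 2 WT arrays cannot be divided, and in the simulations sharing them moved both differences the same way, not in opposite directions. Across all probe sets, which are not independent replicates, the 2 sets of log2 differences had a Pearson r of -0.06. The Spearman rho was 0.04. Simulated values were 0.50 and 0.47, but the simulated groups held no real differences. In the data the differences of Flk1-positive cells from WT embryos had an SD of 0.851. Real differences dilute what shared WT arrays add to r, so the simulated r and rho are not comparable with these. The covariance was -0.0171 against a simulated 0.0299, a difference of -0.047. Both the overlap and the size of the set depended on settings: the overlap was 0 on leaving out any 1 array, and the set held 241 probe sets with the smaller pseudocount and 57 with the larger one.

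**Figure D3:**
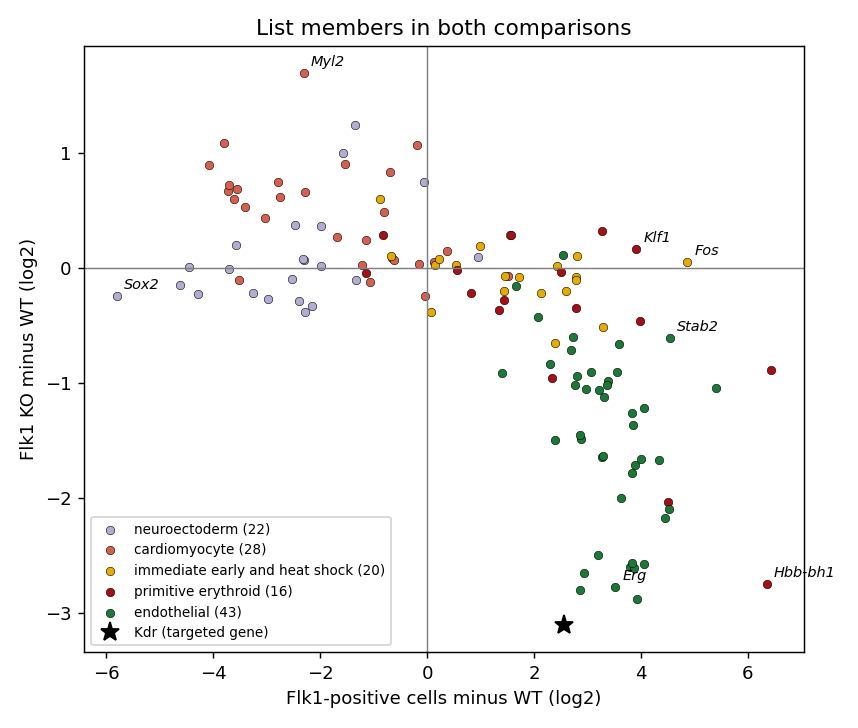
Log2 difference of Flk1-positive cells minus WT embryos (horizontal axis) against that of Flk1 KO minus WT embryos (vertical axis) for the tested members of 5 gene lists and Kdr (star), each point the gene's brightest probe set, 2 arrays per group; both axes share the WT arrays. The endothelial genes lie to the right, most of them below 0 on the vertical axis (median -1.37), the immediate early genes to the right near 0 (Fos at 0.05), and most cardiomyocyte genes to the left and above 0 (median 0.51).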

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

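Leaving out arrays, the scalings and the estimated correlation were fixed before the data were examined, while their limits as tests here, and the other tests in this part, were chosen after the results they bear on had been seen. A control probe set outside the measured genes stood apart: the 5' probe set for 18S ribosomal RNA was 1.43 higher on the log2 scale (1.434) in Flk1-positive cells than in WT embryos, above WT on both arrays. The 3' and middle probe sets for the same RNA differed by 0.74 and 0.38. The 24 poly-A control probe sets, RNAs added during labelling, had a median difference of -0.51 in the same comparison, with both Flk1-positive arrays below both WT arrays for 18 of them, and the 18 hybridisation controls had a median of -0.03. The 3 probe sets for murine repeats lay 0.53, 0.59 and 0.26 higher in Flk1-positive cells and at -0.44, -0.45 and 0.06 in Flk1 KO embryos, each against WT embryos.

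Immediate early genes were higher in Flk1-positive cells, with Fos at 4.86. If endothelial cells of the intact embryo carried these transcripts at that level, Flk1 KO embryos would lose them as they lose endothelial genes of like enrichment. Of the 14 list members called higher, 2 were heat shock genes. Among the 14, 9 above background in WT embryos could be paired with an endothelial gene within 0.5 in enrichment (medians 2.60 and 2.54, WT levels 7.68 and 7.65). The medians in Flk1 KO against WT embryos were -0.105 and -0.911, with the smaller fall in the list member in 8 pairs (exact sign-flip test of the mean pair difference, two-sided, p = 0.016). That p-value treats genes that can change together, on the same arrays, as replicates, so it does not measure the spread between embryos. For these 9, on these arrays, the values argue against intact endothelium as the whole source, unless Flk1 KO embryos raised the same genes elsewhere. The other 5 were not tested. Dissociation and selection of the cells remains a candidate explanation but cannot be told apart from the group, since only this group was made of selected cells, and the 5 heat shock members had a median of 0.221 with 2 higher and 1 lower.

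Blood genes were higher in Flk1-positive cells with no call in Flk1 KO embryos by their brightest probe sets. Levels too near background in WT embryos may hide a fall: 9 of the 25 members called higher lay below background (36%), against 3 of 43 endothelial genes (6.98%; Fisher's exact test, two-sided, p = 0.006). Only 7 members lay at least 2-fold above background, with a median of -0.491 in Flk1 KO embryos, 3 of them at least 2-fold lower and 4 above -0.5, which leaves this explanation open. Blood cells carried along with the selected cells could not be told apart from blood genes active in Flk1-positive cells: 9 of 13 non-globin erythroid members were higher and 2 lower, and the arrays hold no selected cells without Flk1. No sort or gate that would remove blood cells is given in the sources used here.

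Cardiomyocyte genes had a median of 0.51 in Flk1 KO against WT embryos. A smaller share of endothelial cells would raise all other tissues alike. Yet the cardiomyocyte median exceeded that of 56 neuroectoderm, neural crest and somite genes (-0.02) by 0.526 (permutation test over genes, two-sided, p = 2e-05). That p-value treats genes that can change together, on the same arrays, as replicates, so it does not measure the spread between embryos. The mural and mesenchymal (median 0.57) and yolk sac endoderm lists (0.29), which also rose, were not among the 56. The cardiomyocyte median was 0.321 without Flk1 KO replicate 1 and 0.635 without replicate 2, so 1 array alone is not the source. A scaling factor for each array moves all lists alike, so it cannot set the cardiomyocyte median apart from the 3 other lists. The gap was there on the deposited scale, which argues against such a factor as its source. Under quantile normalization the cardiomyocyte median (0.524) stayed 0.477 above the highest of the 3. That setting moved this comparison by a median of only 0.0369, so it adds little. Differences in the stage or dissection of the embryos and an effect of the genotype stay open, untested, and the list's call was lost with an estimated correlation (adjusted p = 0.196).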

How the results depend on the processing

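Values here come from alternatives fixed before the data were examined, and the cause of each change was not tested unless the setting itself gives it. Direction was followed for the lists and for the genes named by the rule, not for the other genes called. None of those past the threshold reversed under any alternative. Kdr values in Flk1 KO are log2 values against a mean below background, so only whether they passed is compared. The endothelial list kept its direction in all 3 comparisons under all alternatives, and lost its call only against an estimated correlation, in both comparisons of Flk1-positive cells. With the smaller pseudocount, Flk1 KO against WT embryos had 0 lower probe sets, the overlap with Flk1-positive cells was 0, the set ordered by size held 241, the correlation across probe sets was -0.0236 and the Kdr difference in Flk1 KO was -3.485, no longer past the threshold. With the larger one these were 68 lower, 6 higher, an overlap of 58, 57 and -0.105, and the Hox list in Flk1-positive cells passed (adjusted p = 0.0404). Without a filter there were 7 lower, an overlap of 7, r = 0.00836, Kdr -3.10 not past the threshold, and adjusted p-values of the Hox list of 0.0338 in Flk1-positive cells and 0.0721 in Flk1 KO. With the filter at the 50th percentile there were 86 lower, 7 higher, an overlap of 79 and r = -0.192. The adjusted p was then 0.0943 for the mural list in Flk1-positive cells and, in Flk1 KO, 0.0037 for the primitive erythroid, 0.007825 for the other blood and 0.986 for the neuroectoderm, p53 and basement membrane lists, the last 3 with reversed direction. Quantile normalization gave 12 lower, an overlap of 12, r = -0.0401, Kdr -3.05 not past the threshold, and in Flk1 KO a Hox adjusted p of 0.093 and reversed somite (0.936) and basement membrane lists (0.779). Median centring gave 14 lower, an overlap of 14, Kdr -3.00 not past the threshold, Hox adjusted p-values of 0.033 in Flk1-positive cells and 0.0907 in Flk1 KO, and in Flk1 KO an erythroid adjusted p of 0.0117 and a reversed cell cycle list (0.711). An intensity trend with a robust prior gave 121 lower, 13 higher and an overlap of 102, a Hox adjusted p of 0.0311 in Flk1-positive cells, and in Flk1 KO an erythroid adjusted p of 0.00962 and a reversed basement membrane list (0.939). Fitting only the 2 groups compared, which leaves fewer samples for the spread, gave 0 lower, an overlap of 0, Kdr -3.10 not past the threshold, a venous adjusted p of 0.0552 in Flk1 KO and a reversed sex-linked list in Flk1-positive cells against WT (0.99). With 1 probe set per gene, which tests fewer probe sets, the counts were 2153 higher and 3113 lower for Flk1-positive cells against WT, 2219 and 3289 against Flk1 KO, 1 higher in Flk1 KO, 79 in the set ordered by size and r = -0.122. A 2-fold limit left 2198 and 2619, and 2640 and 2753, and the set held 406 at 1.5-fold and 58 at 3-fold. With the median over a gene's probe sets the Hox list in Flk1-positive cells had an adjusted p of 0.0407, and in Flk1 KO the erythroid list 0.0425, the endocardial list 0.13 and the BMP and TGF-beta list 0.0792. The immediate early, cell cycle and basement membrane lists (0.855 each) reversed in Flk1 KO, as did Nfatc1 (0.0705) and Kif11 (0.00773), neither past the test. An estimated correlation, which rests on 3 residual degrees of freedom, ended 41 of 42 list calls. The test statistic then also has only 3 degrees of freedom. In Flk1-positive cells against WT, calls ended on both sides of the preset 0.01, with estimates of -0.017 for basement membrane and 0.19 for other blood. These losses therefore cannot be put down to correlation between genes alone. For Flk1-positive cells against WT the adjusted p was 0.0536 (endothelial, somite, immediate early, basement membrane), 0.0712 (neuroectoderm, gut and yolk sac endoderm), 0.0791 (neural crest), 0.0818 (venous, erythroid), 0.087 (other blood, BMP), 0.1004 (cardiomyocyte), 0.117 (arterial, endocardium) and 0.137 (mural). For Flk1 KO against WT it was 0.118 (mural), 0.164 (yolk sac), 0.196 (arterial, cardiomyocyte), 0.226 (venous, endocardium, BMP) and 0.383 (Hox). For Flk1-positive cells against Flk1 KO it was 0.05997 (endothelial, somite, immediate early, basement membrane), 0.0632 (mural, neuroectoderm, neural crest, gut and yolk sac endoderm), 0.0715 (venous, erythroid), 0.0764 (other blood, cardiomyocyte, BMP), 0.0847 (arterial), 0.0979 (endocardium) and 0.167 (Hox).

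Leaving out each array in turn, which assumes that a lone array varies like the other groups, gave 2049 to 4075 higher and 2210 to 4861 lower for Flk1-positive cells against WT, and 2521 to 3884 higher and 3288 to 3972 lower against Flk1 KO. In Flk1 KO against WT it gave 0 to 0 lower and an overlap of 0 to 0, with Kdr from -3.47 to -2.73 and never past the threshold, and r from -0.0948 to 0.0527. Adjusted p-values ranged from 0.0221 to 0.05205 for the mural, 0.0114 to 0.107 for the Hox and 0.695 to 0.986 for the sex-linked list in Flk1-positive cells against WT, and from 0.215 to 0.899 for the sex-linked list against Flk1 KO. In Flk1 KO against WT they ranged from 0.00985 to 0.237 (venous), 0.00514 to 0.65 (erythroid), 0.00475 to 0.761 (other blood), 0.026 to 0.278 (BMP), 0.0197 to 0.329 (Hox), 0.0331 to 0.43 (Notch), 0.0378 to 0.961 (hypoxia), 0.186 to 0.883 (gut endoderm), 0.186 to 0.924 (sex-linked), 0.418 to 0.924 (p53), 0.741 to 0.964 (cell cycle), 0.854 to 0.969 (somite) and 0.9002 to 0.969 (basement membrane). Of these, the sex-linked (in each comparison), gut endoderm, hypoxia, other blood, somite, cell cycle, p53 and basement membrane lists changed direction in at least 1 case. Without Flk1 KO replicate 1, Cer1 and Hoxc9 in Flk1 KO against WT and Eif2s3y and Uty in Flk1-positive cells against Flk1 KO changed sign (ranges -0.843 to 0.131, -0.0247 to 1.23, -0.154 to 1.13 and -0.232 to 0.73). Replicate numbers do not pair the samples: the labels name no shared litter, and the correlations of replicate differences between groups were 0.029, 0.00801 and 0.0226. With the replicate number as a block (replicate block), Flk1 KO against WT had 0 lower and an overlap of 0, Kdr was -3.10 and not past the threshold, the erythroid list passed (adjusted p = 0.0374) and the cell cycle list reversed (0.989). Signal over background limits the Flk1 KO comparison, since 22 of 43 endothelial genes lay below the background level in Flk1 KO embryos and 3 in WT embryos.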

Other observations

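Genes below were named after their values were seen, outside the rule for named genes. Of 120 genes at least 8-fold higher in Flk1-positive cells than in WT embryos, 92 lay above background in WT embryos, and these had a median log2 difference of -1.18 in Flk1 KO against WT embryos, with 50 at -1 or below. Only 6 of the 92 lay above -0.2: the immediate early gene Fos (0.05), the flow-responsive factor Klf2 (-0.13), Plac1 (-0.08), the metalloprotease gene Adam12 (0.06), the laminin gene Lama4 (-0.09) and Npl (0.13). Their differences in Flk1-positive cells against WT embryos were 4.86, 3.64, 3.62, 3.47, 3.34 and 3.06, and whether they differ from the other 86 was not tested.

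The set ordered by size held genes outside the gene lists. Exoc3l, Exoc3l2 and Exoc3l4, relatives of an exocyst subunit, were 3.14, 3.30 and 3.24 higher in Flk1-positive cells than in WT embryos, and at least 1.24-fold, 1.60-fold and 1.80-fold lower in Flk1 KO embryos, whose means lay below background. The growth factor gene Igf1 was in the set with 2 probe sets, 4.02 and 4.28 higher in Flk1-positive cells and at least 3.35-fold and 2.55-fold lower in Flk1 KO embryos. None of these Flk1 KO values passed the limma test (adjusted p from 0.0878 to 0.3). Probe sets at least 2-fold lower than WT in both groups, with arrays that did not overlap, numbered 32 against 12.5 on average and at most 21 in simulations of unchanged groups. They included the left-right and node signalling genes Nodal (at least 3.13-fold lower in Flk1-positive cells, -1.12 in Flk1 KO) and Lefty1 (-1.66 and -1.87) and 2 probe sets of the RNA processing gene Nudt21 (-2.18 and -1.48, -1.82 and -1.26). None of these Flk1 KO values passed the limma test (adjusted p = 0.593, 0.598, 0.236 and 0.196), nor did Lefty1 in Flk1-positive cells (adjusted p = 0.171). Those at least 2-fold higher in both numbered 42 against 13.2 on average and at most 25 in simulations. In these simulations Flk1-positive cells did not differ from WT embryos. In the data 2619 probe sets were called at least 2-fold lower in them and 2198 at least 2-fold higher. The counts of 32 and 42 can therefore exceed the simulated ones without changes shared by both groups.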
